A study of Mus musculus with 2 samples.

How the data were processed

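Single CD4 T cells specific for the 2W1S peptide had been purified from the spleen and peripheral lymph nodes of C57BL/6 mice colonized with Candida albicans carrying that peptide, and were sequenced after capture on a Fluidigm C1 instrument with SMART-Seq v4 chemistry, per the labels. This chemistry reads whole transcripts and adds no molecular identifiers. The 2 samples of the series, a March and an April capture, carried the same treatment label and were treated as replicates 1 and 2 of 1 group. The month was handled as a batch and not tested. Nothing in the labels says how many mice gave each pool, so p-values measure only the spread between these captures, which may be technical.

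The deposited table held log2 values for 12432 genes in 178 cells. The labels name genome build mm10 per the submitters' processing notes; the aligner and the counting program are not given in the sources used here. Taking 2 to the power of each value and subtracting 1 gave sums between 892206 and 979888 per cell, so the values were read as the log2 of a TPM-like value plus a pseudocount of 1; this reading comes from the values and not from a header. Here the linear value means that back-transformed number. Every gene's 4th-highest value was at least 2.0003 on the log2 scale, which points to a gene filter applied before deposit, and genes outside the table were not analysed here. Gene identifiers were Ensembl IDs, of which 12163 were matched to symbols and 269 were not. Coordinates come from GENCODE vM21, the same build. All columns carried a capture month in their names, 0 were left unmapped, and the names also showed 4 runs, Mar1 and Mar17 within March and Apr13 and Apr21 within April. Runs within a capture count as 1 replicate.

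Cells with under 500 genes detected or a total below 5% of the median were to be left out, and 0 were. No doublet caller was run; no pair of cells held identical values, and the highest Pearson correlation between any 2 cells was 0.522. A gene was called detected at a value above 0, or, as an alternative, at a linear value of at least 1. Of all values above 0, 36.6% lay below a linear value of 1. Shares of cells carry exact Clopper-Pearson 95% intervals, which cover counting error only. No p-value of a gene or list took cells as replicates. The rank correlations, the standard errors over cells, the reassignments and the shuffles do take single cells as the unit and say nothing about the spread between mice.

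Differences between classes of cells were tested on the mean of the deposited log2 values per capture and class, which made 4 pseudobulk libraries with the capture as a block. limma 3.58.1 in R 4.3.3 was used with a mean-variance trend and Benjamini-Hochberg adjustment at 0.05, two-sided, over genes detected in at least 10% of cells. With 1 residual degree of freedom per gene, the test leans on the variance shared across genes. The stated differences are differences of mean log2(value + 1) with zeros included and are not folds. Gene lists fixed before the data were examined were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, leaving out the gene that defined the classes and lists with fewer than 3 tested members. With these 4 libraries, camera at an estimated correlation rests on that 1 residual degree of freedom and could hardly call any list. Tested on simulated data in which 200 of 10795 genes were shifted in randomly assigned Klf2 classes, the test recovered 0.5% of genes shifted by 1, 88% of those shifted by 2 and 100% of those shifted by 3. For Foxp3 classes of the real sizes and the same 10795 genes, recovery was 0%, 3.5% and 75.5%.

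Spearman rho with Klf2 was computed in each capture over 6911 genes detected in at least 25% of cells in both captures, and 200 reference genes detected in a similar share of cells gave the spread of the agreement between captures. In simulated data 100% of 50 planted genes were among the 50 highest. Each planted gene was Klf2 itself plus noise with the SD of Klf2, a close tie by construction. The highest mean rho of a real gene was 0.285, and recovery of weaker ties was not tested. List medians were compared with 10000 random lists matched on mean value. Cells were clustered with Leiden (scanpy 1.11.5, leidenalg 0.10.2) on a 15-neighbour graph of 10 components of the 2000 most variable genes, centred within each capture, at resolution 0.8. A cluster was given a cell type name only when at least 3 markers of 1 type were among its 50 leading genes and its 10 leading genes did not go against the name. The markers were fixed in advance; the window of 50 genes was not. Other steps used Python 3.11.15, SciPy 1.17.1 and numpy 2.4.6.

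Genes were named by a rule fixed before the data were examined. It covered, for each class comparison, up to 12 genes per direction past the threshold and, where fewer passed, up to 6 per direction with the smallest p. It also covered 20 fixed regulators and markers, up to 4 members of each list past its test, the 5 genes with the largest difference each way between captures, and the 10 highest and 5 lowest mean rho. Predicted genes, ribosomal pseudogenes and receptor V and J segments were not named under it. Any other gene is said to have been chosen later.

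Alternatives set in advance changed the block, the detection filter, the pseudocount, the averaging scale, the normalization, the detection level, the matching of cells on genes detected, the split of Klf2 values, the cells included and the clustering parameters. Added after the data were seen were the 4 runs as blocks, the removal of 3 cells made up mostly of mitochondrial RNA, and the removal of the Mar1 cells.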

Results

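The series asked what distinguishes CD4 T cells that recognise a peptide displayed by a gut-colonizing fungus, with Klf2, a transcription factor tied to T cell quiescence and recirculation, in its title. Transcriptomes of 178 sorted 2W1S-specific CD4 T cells were available, 82 from the March capture and 96 from the April capture. No uncolonized or other control group was analysed here, so all comparisons below are between cells of colonized mice. The median number of genes detected per cell was 5344 in March (range 2927 to 6990) and 4933.5 in April (range 4005 to 6772). The 10 most abundant genes took a median of 14.6% of the linear signal in March cells and 15.4% in April cells. In 3 cells, all in the run named Mar1, mitochondrial genes took 65.8% to 93.9% of the signal, against at most 38.2% in any other cell. The authors deposited log2 values and not read counts, so the number of reads behind each value is unknown.

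The first question was whether the sorted cells carried the transcripts of CD4 T cells. Cd3d and Cd3g were detected in 100% of cells, and 0 cells lacked all of Cd3d, Cd3e and Cd3g. Cd4 was detected in 92.7% of March and 89.6% of April cells, and at a linear value of at least 1 in 72.0% (95% interval 60.9% to 81.3%) and 69.8% (59.6% to 78.7%). Cd8a reached a linear value of 1 in 6.10% of March cells (2.01% to 13.7%) and 7.29% of April cells (2.98% to 14.4%). Low values were widespread: Ebf1, a B cell gene, was above 0 in 99.4% of all cells with a median log2 value of 1.88 in March and 1.66 in April, and Itgam, a myeloid gene, was above 0 in 77.0% of cells. Detection at a low value therefore did not separate cell types in these data. Ebf1 was at a linear value of 1 or above in 88.8% of cells, so the higher level did not remove that signal either.

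Transcripts of several T cell states were found in the same pools. The median member of the quiescence list was detected in 85.4% of cells, of the central memory or naive list in 77.0%, of the activated list in 64.6% and of the follicular helper list in 58.7%. Other lists came close, with 60.1% for Th2, 50.8% for Tr1, 50.3% for regulatory T cells and 46.6% for the 3 myeloid genes analysed. Such medians count any value above 0 and only members in the table, so they do not show which states the cells were in. Tcf7, Lef1 and Satb1, chosen later, reached a linear value of 1 in 97.2%, 92.7% and 69.7% of cells, against 15.7% for Pdcd1. Icos and Maf were detected in 100% of cells, and at a linear value of at least 1 in 82.6% and 86.0%. Cd44, a marker of antigen-experienced T cells, was detected in 94.4% of cells and reached a linear value of 1 in 52.8%. Cxcr5, a receptor for follicular homing, reached a linear value of 1 in 24.4% of March cells (15.6% to 35.1%) and 41.7% of April cells (31.7% to 52.2%). Ctla4 was detected in 82.0% of cells, Cd69 in 84.3%, Lag3 in 48.3% and Il2ra in 44.9%.

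**Figure D1:**
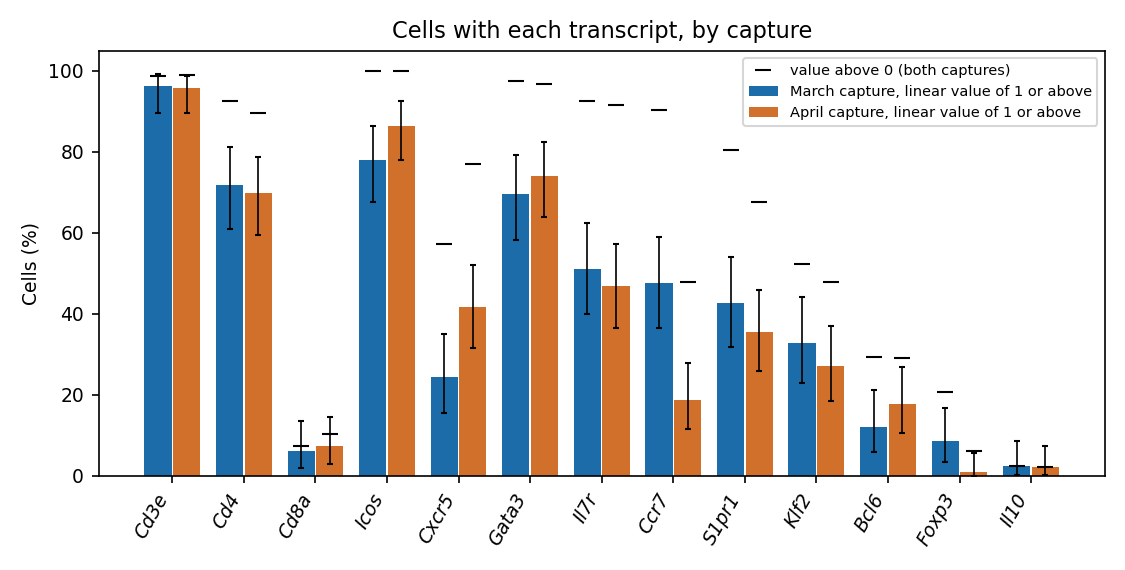
Percent of cells with each transcript in the March (blue, 82 cells) and April (orange, 96 cells) capture. Bars count cells at a linear value of at least 1 with exact 95% intervals, and black dashes count cells with any value above 0; Ccr7 bars stand at 47.6% in March and 18.8% in April.

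The next question was how Klf2 and the lineage regulators fell over the cells. Klf2 (chromosome 8, positions 72319033 to 72321656, mm10) was detected in 43 of 82 March cells, 52.4% (41.1% to 63.6%), and in 46 of 96 April cells, 47.9% (37.6% to 58.4%). Its values were spread widely: 27 March cells, 32.9% (22.9% to 44.2%), and 26 April cells, 27.1% (18.5% to 37.1%), held Klf2 at a linear value of at least 1, and the median log2 value in those cells was 5.14 in March and 5.15 in April. The remaining 16 March and 20 April cells with Klf2 lay below that level.

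**Figure D2:**
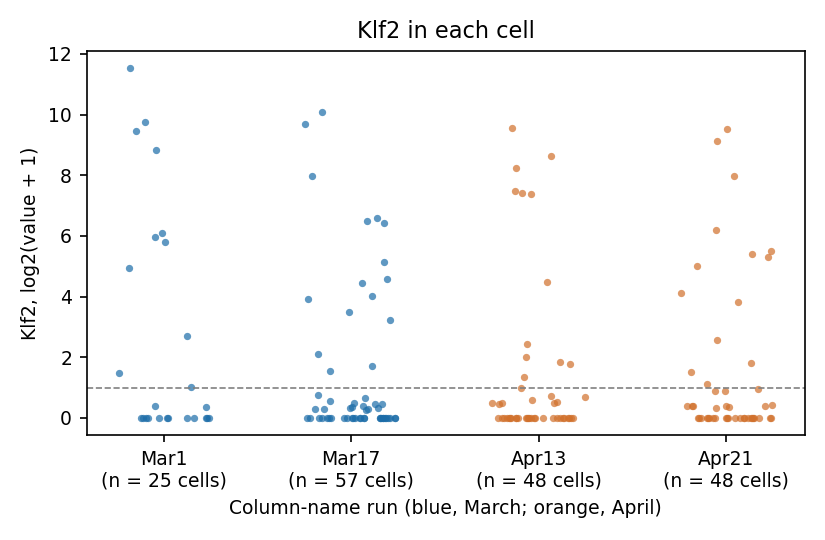
Klf2 as log2(value + 1) in each of the 178 cells, by the run given in the column names, with a dashed line at a linear value of 1. Each run holds cells at 0, cells just above 0 and a group well above the line, with a highest value of 11.53 in Mar1.

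Gata3 was nearly universal, at 97.6% of March and 96.9% of April cells, and reached a linear value of 1 in 69.5% and 74.0%. Bcl6 was detected in 29.3% of March cells (19.7% to 40.4%) and 29.2% of April cells (20.3% to 39.3%). Foxp3 was detected in 17 of 82 March cells, 20.7% (12.6% to 31.1%), and 6 of 96 April cells, 6.25% (2.33% to 13.1%), and at a linear value of 1 in 8.54% and 1.04%. Il10 was detected in 2 cells of each capture, 2.44% (0.297% to 8.53%) and 2.08% (0.253% to 7.32%). Tbx21, Ifng, Il17a and Prdm1 were not analysed here.

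Cells with and without Klf2 were then compared for these regulators. Foxp3 was detected in 20.9% of Klf2-positive and 20.5% of Klf2-negative March cells, and in 2 of 46 and 4 of 50 April cells, with overlapping intervals in both captures. Bcl6 was detected in 30.2% and 28.2% of March cells and in 21.7% and 36.0% of April cells. At a linear value of at least 1, Klf2 and Foxp3 were found together in 1 of 27 Klf2-positive March cells and in 0 of 26 April cells, which leaves room for a share of up to 13.2% in April.

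Gene expression was compared between Klf2-positive and Klf2-negative cells of the same captures. The classes had similar numbers of genes detected, with a median of 5364 against 5294 genes in March and 4936.5 against 4932 in April. Of 10795 genes, 0 other than Klf2 passed an adjusted p of 0.05 in limma; 698 had an unadjusted p under 0.05, and the smallest adjusted p was 0.593. Uniform p-values would give 539.7 such genes, but 100 random assignments of cells to the classes gave a median of 574.5, and 8 of them gave 698 or more. The genes with the smallest p, none of which passed, were Fen1, Nme2, Zfp318, Ap3m2, Map2k3 and Smim4 among those higher in Klf2-positive cells. Among those lower were Bcl2a1b, Trac, Eif2s2, Ppp2r2a, Sla and Hscb. Nme2 was higher by 1.74 ± 0.49 (SE) and Bcl2a1b stood at -1.87 ± 0.45, each with the same sign in both captures. The T cell receptor alpha constant gene Trac stood at -1.20 ± 0.31, with -1.24 in March and -1.16 in April. After quantile normalization Trac alone was called, at -1.35 with an adjusted p of 0.0292 in limma.

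Of the regulators and markers fixed in advance, the cytokine receptor gene Il7r had the largest positive difference that went the same way in both captures. It was 1.27 higher in Klf2-positive cells (95% interval 0.36 to 2.19), with 1.54 in March and 1.01 in April, and its adjusted p was 0.593 in limma. Ccr7 was higher by 0.78 ± 0.39, with 1.04 in March and 0.52 in April. Cd44 stood at -0.89 ± 0.46 and Foxp3 at -0.35 ± 0.15, negative in both captures. Il2ra differed by 0.21 and Maf by -0.86. Gata3, Bcl6, S1pr1, Cd69, Lag3 and Ctla4 had opposite signs in March and April. S1pr1, an established target of Klf2, was -0.50 in March and 0.64 in April. Il10 was in too few cells to be tested.

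Gene lists were tested because shifts of many genes can be seen where single genes are not. Of 27 lists, 7 passed camera with the preset correlation in limma, and none of these calls held with an estimated correlation (adjusted p = 0.885 for each of the 7) or in the directional test of fry. The estimated correlation also gave 0 lists in each of 100 random assignments of cells, so its 0 does not tell real classes from random ones. With the preset correlation, quiescence and trafficking genes were higher in Klf2-positive cells (adjusted p 0.000564), with a median difference of 0.34 in March, 0.41 in April and 0.23 for the mean of both. Of its 19 members 16 were higher by that mean, and the same 8 genes were higher in both captures. With cells matched on genes detected the list median was 0.10. Central memory or naive genes (0.48 and 0.25, adjusted p 0.00571), Klf2-linked genes (0.28 and 0.38, adjusted p 0.0099) and ribosomal protein genes (0.24 and 0.16, adjusted p 0.00153) were also higher. The ribosomal call rested on few cells: without the 3 mostly mitochondrial cells the list median went from 0.21 to -0.01 (adjusted p 0.207), without the Mar1 cells to -0.03 (0.488), and after quantile normalization to 0.03 (0.604). The oxidative phosphorylation list, not called with all cells (-0.38, adjusted p 0.156), was lower past the threshold without the mitochondrial cells (-0.48, adjusted p 0.0234, and 0.895 with an estimated correlation) and in 3 of the other 14 alternatives. Without the Mar1 cells the central memory list had a median of 0.19 and an adjusted p of 0.062. The interferon response list was higher with an adjusted p of 0.000316, but its median was 0.47 in March and -0.02 in April. Exhaustion and anergy genes were lower (-0.22 and -0.46, adjusted p 0.0099), and so were regulatory T cell genes (-0.51 and -0.09, adjusted p 0.048). The regulatory T cell call was lost in 9 of 15 alternatives, among them the fit without the replicate block (adjusted p 0.0729), without the mitochondrial cells (0.0604) and without the Mar1 cells (0.142). Without Foxp3-positive cells its median went from -0.35 to -0.17 (adjusted p 0.307). With linear values averaged in place of logs, the interferon list alone passed. The lists share members, since Klf3 and Ccr7 belong to 2 or more of them.

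**Figure D3:**
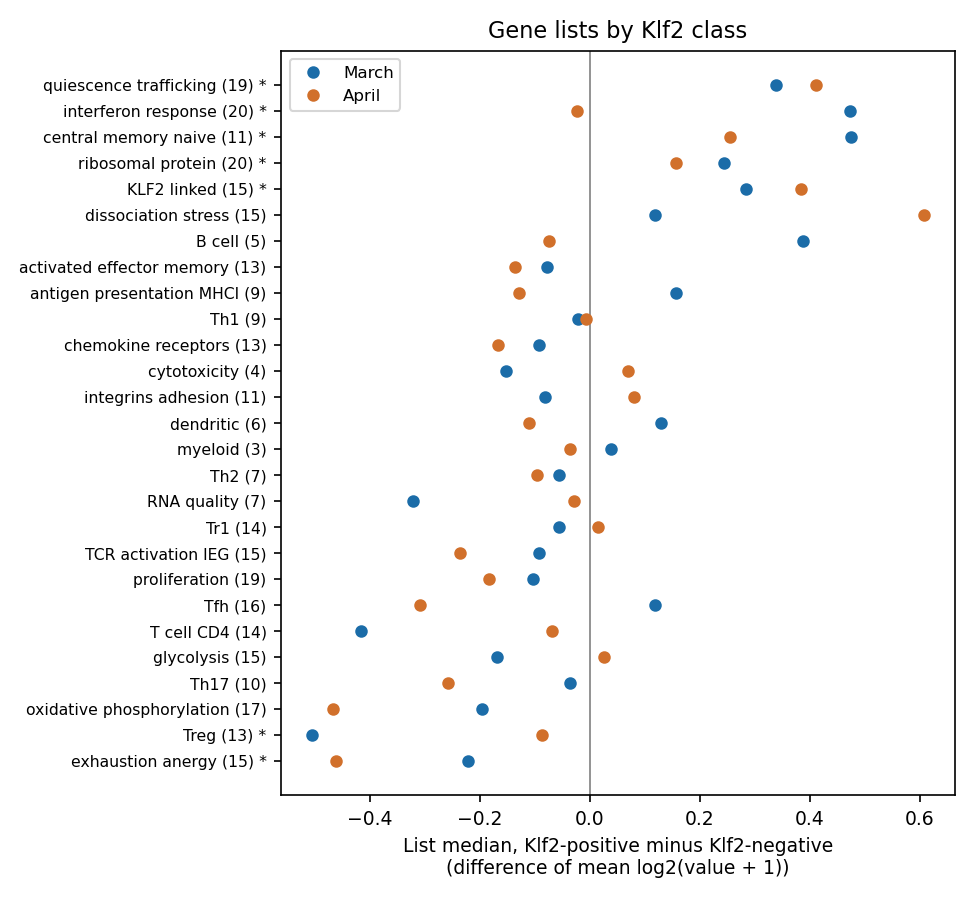
Median over each list of the difference of mean log2(value + 1), Klf2-positive minus Klf2-negative cells, in March (blue) and April (orange), with the number of tested members in brackets and a star for lists past camera with the preset correlation. The quiescence and trafficking list lies at 0.34 and 0.41, and the exhaustion and anergy list at -0.22 and -0.46.

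Members with the smallest p in these lists did not pass over all genes. In the quiescence list they were Il7r, Dgka (1.27 ± 0.52), Actn1 (0.98 ± 0.41) and Klf3 (0.82 ± 0.40). Emp3 (-1.26 ± 0.50), Itgae, Klf3 and Ccr7 led the Klf2-linked list, and Emp3 went against its list. Il7r, Actn1, Ly6c1 (-0.47 ± 0.21) and Ccr7 led the central memory list. Ikzf2 (-1.10 ± 0.34), Foxp3, Itgae (0.34 ± 0.16) and Tnfrsf4 led the regulatory T cell list, and Ikzf2, Egr2 (-0.70 ± 0.27), Pdcd1 (-0.69 ± 0.30) and Nr4a3 the exhaustion list. Ifi27l2a (1.19 ± 0.42), Slfn5, Rtp4 and Irf7 led the interferon list, and Rplp1, Rps24 and Rpl5 were among the leading members of the ribosomal list. Adjusted over the list alone, 4 calls were made against 0 over all genes tested: Trac in the CD4 T cell list, Ikzf2 in both the regulatory T cell and the exhaustion list, and Pgk1 in the glycolysis list (-1.54 ± 0.44).

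When Klf2-positive was taken as a linear value of at least 1, 11 lists passed camera with the preset correlation and 0 with the estimated correlation (adjusted p = 0.709). The 7 lists above were among them, the quiescence list with a median difference of 0.65 and an adjusted p of 4.6e-07. The other 4 were the follicular helper (-0.27), CD4 T cell (-0.50) and glycolysis (-0.23) lists, which were lower, and the dissociation stress list (0.22), which was higher.

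Foxp3-positive and Foxp3-negative cells were compared as a check of the method on a known lineage, with 17 against 65 cells in March and 6 against 90 in April. In limma, 0 of 10795 genes passed, 687 had an unadjusted p under 0.05 where uniform p-values would give 539.7, and the smallest adjusted p was 0.43 for the interferon-induced GTPase gene Igtp, at 3.28 ± 0.80. Foxp3 itself, which defined the classes, did not pass (1.84 ± 0.55, adjusted p 0.771). After Igtp, and leaving Foxp3 out, the smallest p of higher genes belonged to Mea1, Mrpl52, Rpp25l, BC005537 and Xlr4a, and of lower genes to Tspyl1, Hist1h4d, Mospd3, Fbxo7, Cbx7 and Apip. The regulatory T cell list without Foxp3 was not past camera (adjusted p 0.555, median difference 0.08 in March and 0.02 in April), and Il2ra differed by 0.28 ± 0.51. At this class size the method thus did not recover the known lineage list, and Foxp3 lay below a linear value of 1 in 10 of the 17 March and 5 of the 6 April cells counted as positive.

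In the Foxp3 comparison 2 lists passed camera with the preset correlation and 0 with fry or with the estimated correlation (adjusted p = 0.912). None passed without the replicate block, with averaged linear values or without the Mar1 cells. The interferon response list was higher (median 0.58 in March and -0.04 in April, adjusted p 0.0367), led by Igtp, Ifi47, Zbp1 and Slfn5, the last of these lower. The quiescence list was lower (-0.19 and -1.03, adjusted p 0.0367), led by S1pr4 (-1.80 ± 0.65), Il7r (-1.68 ± 0.73), Itgb7 (1.61 ± 0.79) and S1pr1 (-1.16 ± 0.68). The RNA quality list, of which mitochondrial transcripts were tested, had a median of -0.43 with 0 of 7 members higher (adjusted p 0.0974), and was past the threshold with a pseudocount of 10 (0.0164) and with 4 runs as blocks (0.0356). Camera with an estimated correlation gave adjusted p-values of 0.924 and 0.656 for those settings. Klf2 differed by -1.39 in March and 0.18 in April. Adjusted over the list alone, 3 calls were made (Igtp, Ccr8 and Stat6), and 0 over all genes tested. S1pr1, Il7r, Cd69 and Il2ra kept their sign in both captures, while Klf2, Gata3, Bcl6, Ccr7, Cd44, Lag3, Ctla4 and Maf did not.

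Correlation with the level of Klf2 was computed in each capture as a reading that needs no classes. Across genes, which are not independent replicates, rho in March and rho in April correlated at 0.0312, within the spread of 200 reference genes (median 0.0292, SD 0.0547; Klf2 at percentile 51). The order of single genes was therefore not reproduced between captures beyond what unrelated genes show. Among the genes of highest mean rho were Uhrf1bp1l (0.285), Ap3m2 (0.283), Ifi213, Slfn5, Crim1, Orai2, Osbpl9, Rpl13 and Itga2b. The lowest belonged to Slc41a1 (-0.310), Eif2s2 (-0.294), Mgrn1, Wsb2 and Emilin1. List medians were set against random lists, which do not carry the correlation between members of a list. The median rho of the quiescence list was 0.0957 in March and 0.0579 in April, and that of the central memory list 0.111 and 0.0377, each at percentile 100 of matched random lists by mean rho. The interferon (0.153 and 0.0209) and Klf2-linked (0.034 and 0.0629) lists stood at percentiles 99.95 and 99.6. At the other end were the exhaustion list (-0.0454 and -0.105, percentile 0.3) and the Th17 list (-0.0839 and -0.12, percentile 0.69).

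The cells fell into 7 clusters of 45, 33, 28, 26, 20, 18 and 8 cells, described here without a test. The first component held 4.75% of the variance and all 10 components 14.4%, so the clusters were weakly separated. Cluster 2 was follicular helper-like, with Cxcr5, Pdcd1, Sh2d1a, Btla and Izumo1r among its 50 leading genes. Maf and Tigit, which with Pdcd1 belong to the Tr1 list, were also among them. The cluster held 18.3% of March cells (10.6% to 28.4%) and 18.8% of April cells (11.5% to 28.0%). Its size depended on the settings: without centring within captures the cluster with most follicular helper markers held 5 March and 13 April cells. Clusterings at resolution 0.4 or 1.2, with 20 components or without centring had adjusted Rand indices between 0.181 and 0.51 with this one. Cluster 5 was activated-like by the naming rule, with Lgals1, Crip1 and Vim, and the regulatory T cell list member Capg, among its leading genes. Under that rule a program list such as proliferation could not name a cluster. The proliferation list members Stmn1 and Hmgb2 were among the 10 leading genes of cluster 5. Its cells had the highest median of genes detected (5698). All 19 proliferation genes (median difference 3.04) and all 17 oxidative phosphorylation genes (2.75) were above the other cells, against 2.08 for the activated list. All 20 ribosomal protein genes were above too (0.51). Only 3 of 15 dissociation stress and 5 of 15 exhaustion genes were, so the rise did not extend to all lists. The part of depth in it was not tested. Cluster 5 held 7.32% of March cells (2.73% to 15.2%) and 14.6% of April cells (8.21% to 23.3%). Cluster 4 had Satb1 and Actn1 together with the activation gene Tnfrsf4 and was left unnamed, as were clusters 1, 3, 6 and 7.

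Klf2 at a linear value of at least 1 was found in 2 of 15 March cells and 1 of 18 April cells of the follicular helper-like cluster. In all other cells it was found in 25 of 67 March and 25 of 78 April cells. Over both captures the shares were 9.09% (1.92% to 24.3%) in the cluster and 34.5% (26.8% to 42.8%) outside it. Under those other clusterings the share inside was between 10.7% and 14.3%, the highest at resolution 0.4, where the March shares were 21.4% (4.66% to 50.8%) inside and 35.3% (24.1% to 47.8%) outside. Counting any value above 0, the cluster's share was 45.5% (28.1% to 63.6%), so the difference was in cells with a substantial level. These intervals treat cells as independent draws, and no test between captures was made.

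**Figure D4:**
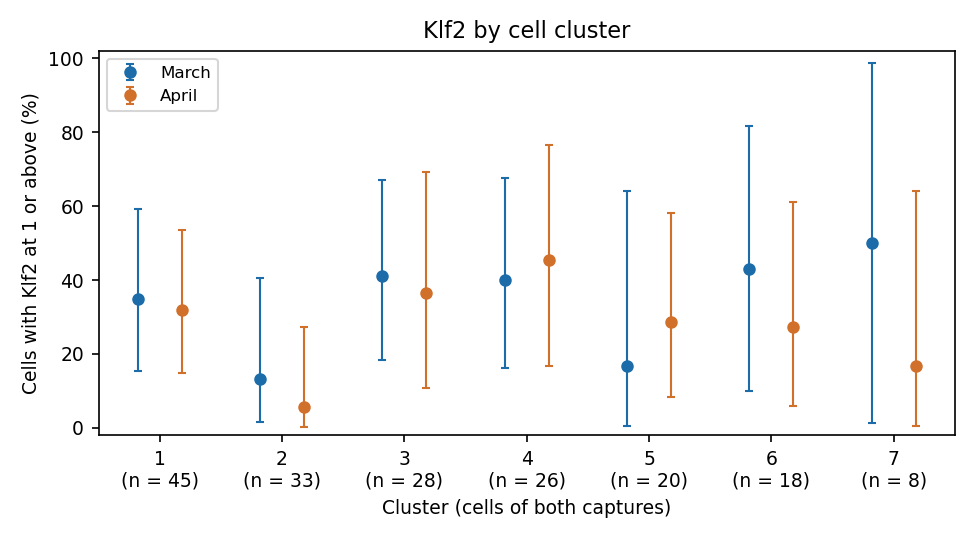
Percent of cells with Klf2 at a linear value of at least 1 in each of the 7 clusters, in March (blue) and April (orange), with exact 95% intervals and the cells of both captures together under each cluster number. The follicular helper-like cluster, number 2, lies lowest in both captures, at 13.3% and 5.56%.

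Because the cells were sorted on 1 peptide, receptor segments were counted by the segment with the highest value in each cell. No Trbv gene was analysed here, and 9 Trav genes were. Trav13d-1 was highest in 24.4% of March cells (15.6% to 35.1%) and 35.4% of April cells (25.9% to 45.8%), Trav13-2 in 25.6% and 32.3%, and Trav8-2 in 19.5% and 15.6%. Reads from near-identical copies of these Trav genes can be split between them, so the split among them is uncertain. For Trbj segments, counted after the data were seen, Trbj2-7 was highest in 26.8% of March cells (17.6% to 37.8%) and 24.0% of April cells (15.8% to 33.7%), and Trbj2-5 in 13.4% (6.89% to 22.7%) and 28.1% (19.4% to 38.2%).

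The captures were finally set side by side as a description of the batch. Mean log2 values of March and April correlated at 0.971 across genes, and those of single runs at 0.938 to 0.958 between months, 0.951 between the March runs and 0.961 between the April runs. Of 7664 genes in at least 25% of cells, 234 were higher by over 1 in April and 63 in March. The largest differences towards April were S100a11 (4.26 in March, 6.84 in April), Jpt1, Dad1, Cnbd2 and Trac (9.07 and 11.08). Towards March they were Foxn3 (3.88 and 1.80), Erich1, Ccr7 (3.03 and 1.37), Ruvbl1 and Lasp1. In 37.2% of these genes both April runs lay on the same side of both March runs, where chance gives 33.3%. By list, the central memory list was lower in April, with a median of -0.61 and 8 of 10 members lower (percentile 0 of matched random lists). The quiescence (-0.25, percentile 0.56) and Klf2-linked (-0.30, percentile 0.73) lists were also lower. The Th17 list was higher by 0.67, with 8 of 8 members higher (percentile 99.99), the follicular helper list by 0.62, with 13 of 15 members higher (percentile 99.99), and the CD4 T cell list by 0.80. Lists of no T cell subset stood out too. The chemokine receptor (0.61, percentile 99.91) and oxidative phosphorylation (0.61, percentile 99.38) lists were higher. Ribosomal protein (0.11, percentile 0.3) and RNA quality (0.10, percentile 0.86) lists were low against random lists. Random members were drawn from the neighbours of each gene in the ranking by mean value, which ends at the highest gene. For the most abundant genes draws past that end all fell on the highest gene, so the percentiles of the ribosomal protein and RNA quality lists cannot be relied on. Month, pool and run cannot be told apart here, and no test was made.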

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

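Added after the data were seen were the 4 runs as blocks, the removal of 3 mostly mitochondrial cells or of the Mar1 cells, clustering without Klf2, and picking cells by the mean of the follicular helper list. Of 85 alternative values of the results that answer a comparison, 68 stayed within the limits set for them and 17 moved. Named genes changed sign in 21 of 384 gene and setting pairs (Klf2) and 12 of 282 (Foxp3); with hardly any gene called, 0 reversed calls say little. The count of genes in the Klf2 comparison was 0 in 14 of 15 alternatives and 1 after quantile normalization (Trac, -1.35); with an unadjusted p under 0.05 there were between 378 and 767 genes. In the Foxp3 comparison it was 0 in 11 of 11, without the replicate block too.

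The 7 lists of the Klf2 comparison fell to 0 with the estimated correlation, 0 with fry and 1 when linear values were averaged, rose to 11 when detection meant a linear value of at least 1, and were between 5 and 8 in the other 13 alternatives, without the replicate block too. The interferon list passed in 15 of 15 alternatives of the fit, the quiescence list in 14, the central memory, exhaustion and Klf2-linked lists in 13 each, the ribosomal list in 11 and the regulatory T cell list in 6. The 2 lists of the Foxp3 comparison became 0 with the estimated correlation, with fry, without the replicate block, with averaged linear values and without the Mar1 cells, 1 with matched cells and 7 with 4 runs as blocks, which treats runs as replicates. The cause was not tested. At a linear value of at least 1 the share of cells with Klf2 was 32.9% in March and 27.1% in April, by construction lower. Resolution 0.4 gave 3 clusters. Counting any Trav gene, Trav13d-1 was in 62.2% of March and 79.2% of April cells.

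Of the 14 tested genes fixed in advance, 8 (Klf2) and 10 (Foxp3) had opposite signs in the captures; each capture alone is 1 pair and gives no test. Count-based tests were not run on log values. Removing cells without Cd3 genes, or under 1000 genes, changes nothing because there are none; Cd79a and Lyz2 were not analysed here, and Foxp3 at a linear value of at least 1 left 1 April cell, too few for a class. The absence of counts and the share of low values limit every statement about detection.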

Other observations

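The test of low Klf2 values and the clustering without Klf2 were set before their results were seen; the other tests below were chosen after, and the bounds of the reassignment and shuffle tests were reworded once their values were known. The lists that separated Klf2-positive from Klf2-negative cells could come from chance, and 100 random assignments of cells within captures were drawn. With the real one included 4 gave at least 7 lists, the highest of the others also giving 7. By fry the real assignment gave 0 lists and random ones up to 2, so chance stays open. The estimated correlation gave 0 lists in the real and in every random assignment and cannot decide this. List by list, the mean difference was as far from 0 in 1 of 100 reassignments for the quiescence list, 2 for exhaustion, 3 for the regulatory T cell list, 6 for central memory and for interferon, 14 for ribosomal proteins and 24 for Klf2-linked genes. With cells matched on genes detected all 7 lists passed in the same direction, but the list median went from 0.23 to 0.10 for quiescence and from 0.23 to 0.11 for central memory, so the sizes of these depend on which cells are used.

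Klf2 values below a linear value of 1 may be background: the quiescence list mean of such cells differed from that of cells without Klf2 by 0.125 in March, where cells at 1 or above differed by 0.453, and by -0.0378 in April, against 0.743. The March ratio lay just over the limit set in advance and the April ratio well under it, with standard errors over cells of 0.334 and 0.246, so the question stays open.

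Follicular helper-like cells may hold less Klf2, a difference noticed in the clusters before it was tested. Their median number of genes detected was within 10% of the other cells (-2.73% in March and -0.566% in April), which argues against fewer genes detected as the reason. The reads per cell are unknown, so depth itself was not tested. When Klf2 was left out of the clustering, the follicular helper-like cluster of 34 cells had a share of 8.82% with Klf2 at a linear value of at least 1, below the interval of the other cells (27.0% to 43.1%), so Klf2 itself was not needed to form the cluster. Of these 34 cells 33 were in the cluster formed with Klf2, so the low share gained no independent support. Picked without clustering, the cells with the highest follicular helper list mean differed from the others by -12.04 percentage points in March and -17.2 in April, with overlapping counting intervals (20.0% against 34.7% over both). A reciprocal relation is a hypothesis, found and tested on the same 178 cells, and the calls of the follicular helper list differ: not with Klf2 above 0 (camera adjusted p 0.329; medians 0.12 in March and -0.31 in April), lower with Klf2 at a linear value of at least 1 (-0.27, adjusted p 0.00185, and 0.709 with an estimated correlation), and past the threshold in 2 of 15 alternatives (adjusted p from 0.00185 to 0.831).

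Cells with Y-linked transcripts (Ddx3y, Eif2s3y, Kdm5d or Uty) and cells with Tsix, which is read opposite Xist on the X chromosome, were counted to ask whether the pools could hold cells of both sexes. At a log2 value of at least 1, 34 cells held both kinds against 39.9 by chance, as few as in 3.69% of 10000 shuffles within captures. At a log2 value of at least 3, 15 did against 17.8, as few as in 21.1%. The levels gave different answers, and the sex of the animals stays untested.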
